A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

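Sequencing of 5′-phosphorylated RNA ends (HT-5PSeq, with reverse transcription from oligo(dT) only, per the labels' protocols) was done on 16 libraries in 8 groups of 2, from cultures grown for 4 h at 30 °C in medium without uracil to an OD600 of 0.7. The deposited gene table holds whole-number read counts per transcript, not normalized by the authors, and the deposited position tables hold counts of 3′ ends and of 5′P ends per position from the stop codon. Per the submitters' processing notes, FastQC, cutadapt, HISAT2, featureCounts, bedtools, MultiQC and SAMtools were used with the sacCer3 (R64) genome; their versions and settings are not given in the sources used here. The annotation header names rtracklayer 1.42.1. Whether reads with the same molecular origin were collapsed is not given in the sources used here, so intervals cover counting error only. The gene table has 5698 rows, of which 5550 of the 5696 host rows matched a gene symbol through the RefSeq table.

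Libraries with fewer than 1000 reads were called near-empty. That left 13 of 16, and 11 with the reporter. Genes were tested with edgeR 4.0.16 (TMM, filterByExpr, glmQLFit, glmQLFTest) in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. Host genes were fitted on the 13 libraries and plasmid rows on the 11. Where a group has 1 library, that library is assumed to vary like the other groups. Alternatives used DESeq2 1.42.0. Gene lists were tested with camera in limma 3.58.1 on voom values (preset correlation 0.01, with the estimated correlation and fry beside it), adjusted over 150 tests of 15 lists in 10 comparisons. Positions were analysed in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. For each library the share of ends at each site and the mean position were computed, then tested by permutation of the F ratio (100000 resamples) over 7 groups and by two-sided exact permutation for modified against WT and for T against no T. Values were adjusted within each gene, over 12 tests for 3′ ends and 15 for 5′P ends. The reading frame was taken over positions more than 20 nt before the stop codon, as the frame most used by the control genes.

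The analysis departs from the design written before the data were examined in the following ways. That design put all 16 libraries in the fits. On data simulated without changes, the fit on 16 made false calls in 25 of 30 tests and the fit on 13 in 2 of 30. The 30 tests were 10 comparisons on each of 3 simulated data sets. The fit on 13 is therefore reported and the fit on 16 is an alternative. The position tests likewise use 11 libraries where 14 were planned. The design named no family for adjusting the reporter's contrasts. They were first adjusted over all rows; adjustment over the 9 reporter contrasts was added after both results had been seen, and calls follow the first. The regions and the frame used for 5′P ends were also set after the tables were seen. With simulated changes of 2-fold, the fit on 13 recovered 93.0% of changed genes for reporter against no reporter, 72.1% for modNNN against WT and 44.3% for modHTH against modNNN, on at least 5244 genes. Each percentage rests on 201 changed genes, drawn only from genes above a minimum read level. A simulation made up to 8, 14 and 2 false calls in these comparisons. In 100 simulations without a shift, the 3 position tests (7 groups, modified against WT, T against no T) passed 0.05 in 4, 1 and 3 cases. With a shift of 5 nt simulated in the libraries with T alone, they passed in 46, 0 and 100. No shift of all modified libraries against WT was simulated, so the power of that test is unknown. The list test found 3 of 3 shifted lists and passed 2 of 150 unshifted ones. Genes were simulated independently of each other, so this does not show how the list test behaves on lists with correlated members. The gene simulations likewise held no difference between libraries shared by many genes. They do not show how often the fit on 13 makes false calls in the data.

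Genes were named by a rule fixed before the data were examined: the reporter, RPS3 and the markers, then up to 12 genes per direction (up to 8 in the contrasts among modified terminators) with the largest change among those with an adjusted p under 0.05 whose libraries do not overlap, up to 4 members with the smallest p from each list that passed camera, and the 3 sites with the highest mean share. The leading sites of each construct follow the same rule within the construct. The lists were cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, Puf3 targets, general stress response, heat shock chaperones, glycolysis, respiratory chain, amino acid biosynthesis, sulfur assimilation, pyrimidine synthesis, RNA decay machinery, cleavage and polyadenylation factors, histones and genes of mating type a. Alternatives covered normalization, filter, tool, libraries, replicate block, coding length, site definition and each library left out. Replicates differed by more than sampling noise (chi-square per degree of freedom 2.91 to 9.66), so no pair was taken for a library deposited more than once. This does not tell separate cultures from repeats of a culture. Figures were drawn with matplotlib 3.10.9.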

Results

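5′-phosphorylated RNA ends were sequenced from budding yeast (strain BY4741) that carried a low copy plasmid with an mCherry reporter under the RPS3 promoter. RPS3 encodes a protein of the small ribosomal subunit, and the reporter ended in the RPS3 terminator, either unmodified (WT) or with 3 insertion sites of 9 bp. The modified terminators combined a random sequence (N) with an ATATTC motif (A), a TTTCATTTC motif (H), a TGTACAATA motif (T) or an insert named G, whose sequence the labels do not give. A plasmid without the reporter, whose label names ccdB, served as the control, so the plasmids may differ in more than the reporter. The assay captures RNA with a 5′ phosphate, mostly decay intermediates, so a read count is not a measure of total mRNA. The 8 groups had 2 libraries each. Of the 16 libraries, 13 held between 1070844 and 2939907 reads. The second libraries of modNGG, modHNH and modHTH held 477, 267 and 69 reads and gave no usable values, so these 3 groups rest on 1 library each. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Of the marker genes deleted in the strain, chromosomal URA3 and MET17 had 0 reads in every library and LEU2 had at most 2. HIS3 had 198 to 582 reads in the 13 usable libraries (mean 176 CPM in modHTH to 249 CPM in modHNH), so it does not go with the other markers. The strain's HIS3 allele is known as a partial deletion, and whether these reads come from the part that remains was not tested.

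The first comparison was of reporter level between terminators. The reporter stood at 8620 ± 638 CPM with the WT terminator (SD, n = 2) and at 6292 ± 345 CPM with 3 random inserts (SD, n = 2). It reached 7747 ± 944 CPM with 1 copy of T (modNTN; SD, n = 2) and 2700 ± 395 CPM with 2 copies of A (modNAA; SD, n = 2). The single libraries gave 8355 CPM for modNGG, 5246 CPM for modHNH and 1948 CPM for modHTH. Reads of URA3, the selection marker on the same plasmid, ranged less, from 4824 ± 349 CPM in modNNN to 6915 ± 1126 CPM in WT (SD, n = 2 each). The reporter row was not counted and plasmid URA3 was listed at 0 in the libraries without reporter, so neither has a background level from that group.

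**Figure D1:**
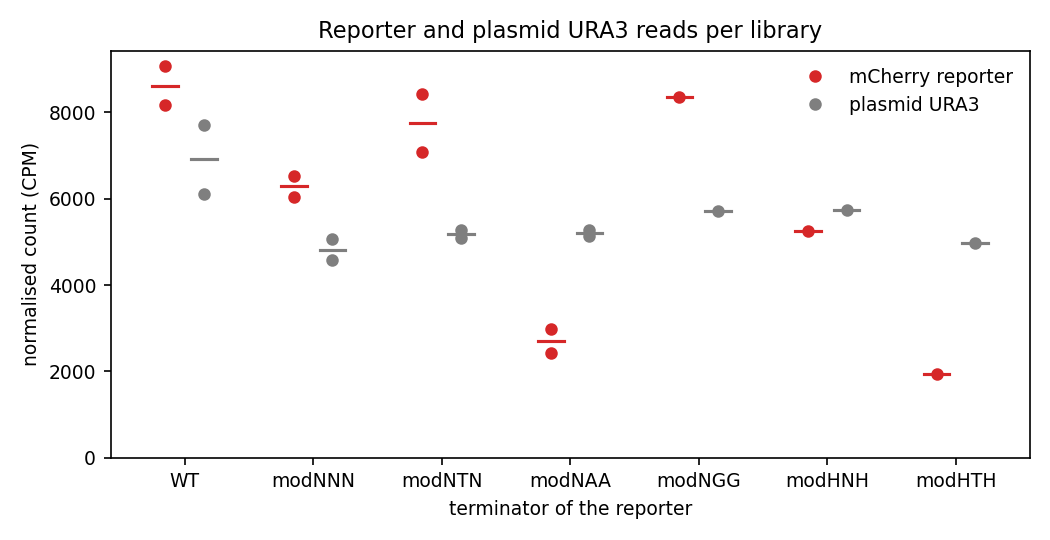
Normalised read counts in CPM (vertical axis) of the mCherry reporter (red) and of plasmid URA3 (grey) for each terminator (horizontal axis). Each point is a library and each line the mean of a group; modNAA (mean 2700) and modHTH (1948) lie below the other terminators in reporter reads.

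The reporter fell in modNAA against modNNN by 1.22 on the log2 scale (SE 0.17), a 2.33-fold lower level, with an adjusted p of 0.030 in edgeR's quasi-likelihood test over all 5262 rows tested. It also fell in modHTH, with log2 fold changes of −1.69 (SE 0.23, edgeR adjusted p = 0.0098) against modNNN and −1.99 (SE 0.23, edgeR adjusted p = 0.0030) against modNTN. The difference between modHTH and modHNH was −1.43 (SE 0.25, unadjusted p = 4.8e-05), which did not pass the threshold over all rows (edgeR adjusted p = 0.25) but passed in DESeq2 (adjusted p = 8.2e-05) and in edgeR with library totals (0.020). Without H, the same T insert gave +0.30 (SE 0.17, edgeR adjusted p = 0.999) in modNTN against modNNN. The difference between these 2 effects of T was −1.73 (SE 0.30, unadjusted p = 4.8e-05, edgeR adjusted p = 0.25; 0.00011 in DESeq2 and 0.016 with library totals). The values for modNGG (+0.41, SE 0.21) and modHNH (−0.26, SE 0.21) against modNNN had edgeR adjusted p-values of 0.41 and 0.56. Random inserts alone gave −0.45 (SE 0.17, edgeR adjusted p = 0.91) against WT, and plasmid URA3 gave −0.52 (SE 0.17) in the same comparison. Per read of plasmid URA3 the reporter stood at 1.27 ± 0.30 in WT and 1.31 ± 0.02 in modNNN (SD, n = 2 each), at 0.518 ± 0.067 in modNAA (SD, n = 2) and at 0.392 in modHTH.

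Which of these pass depends on the tool, the normalization and the number of tests corrected for. Adjusted over the list alone, that is over the 9 reporter contrasts, edgeR's p-values were 0.029 for modNNN against WT and 8.7e-05 both for modHTH against modHNH and for the difference between the effects of T. For modNAA against modNNN, edgeR's p-value adjusted in this way was 1.7e-05. That narrower adjustment was chosen after both sets of values had been seen, so the calls above keep the wider one. The fit first planned, on all 14 reporter libraries with the near-empty ones, called none of the 3 contrasts that pass here. It gave edgeR adjusted p-values of 0.73 for modNAA and 0.25 for modHTH against modNNN and 0.28 for modHTH against modNTN. The fit without near-empty libraries was chosen after the library totals were seen. The modNAA call over all rows was lost when either modNAA library was left out (log2 fold change −1.38 without the first and −1.08 without the second). It was also lost without the first modNNN library (−1.16) or either modNTN library (−1.22 in both fits). The size of the modNAA difference thus changed less than its call. The modHTH calls compare a lone library that is assumed to vary like the others. Against modNNN the call was lost without either modNTN library (edgeR adjusted p = 0.055 and 0.054), and against modNTN without the second modNTN library (0.11). Native RPS3 differed by at most 0.25 on the log2 scale in the contrasts with modNNN, where modHTH gave −0.25 (SE 0.19, edgeR adjusted p = 0.52).

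The second comparison was of where the reporter's transcripts ended. With the WT terminator, the leading 3′ end lay 59 nt after the stop codon and held 31.5% ± 2.6 of ends (SD, n = 2), followed by sites at 49 nt (9.92% ± 0.39) and 63 nt (7.87% ± 1.06). In 5 of the 6 modified terminators the leading end lay at 75 or 76 nt. The site at 75 nt held 19.3% ± 0.1 of ends in modNNN, 20.5% ± 0.8 in modNAA and 37.5% ± 0.9 in modNTN (SD, n = 2 each), against 0.0489% ± 0.0090 in WT (SD, n = 2). It held 29.9% in modHTH (95% Wilson interval 28.0 to 31.8), 21.2% in modNGG (20.6 to 21.8) and 14.7% in modHNH (13.9 to 15.6). The modHNH reporter ended most often at 55 nt, with 19.1% of ends (18.2 to 20.1), and the modNGG reporter at 76 nt, with 26.2% (25.6 to 26.9). The mean 3′ end position was 58.3 nt in both WT libraries and between 62.9 nt (modHNH) and 74.7 nt (modNGG) in the modified groups. The inserts lengthen the terminator, so a later position in a modified terminator is not by itself another choice of site.

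**Figure D2:**
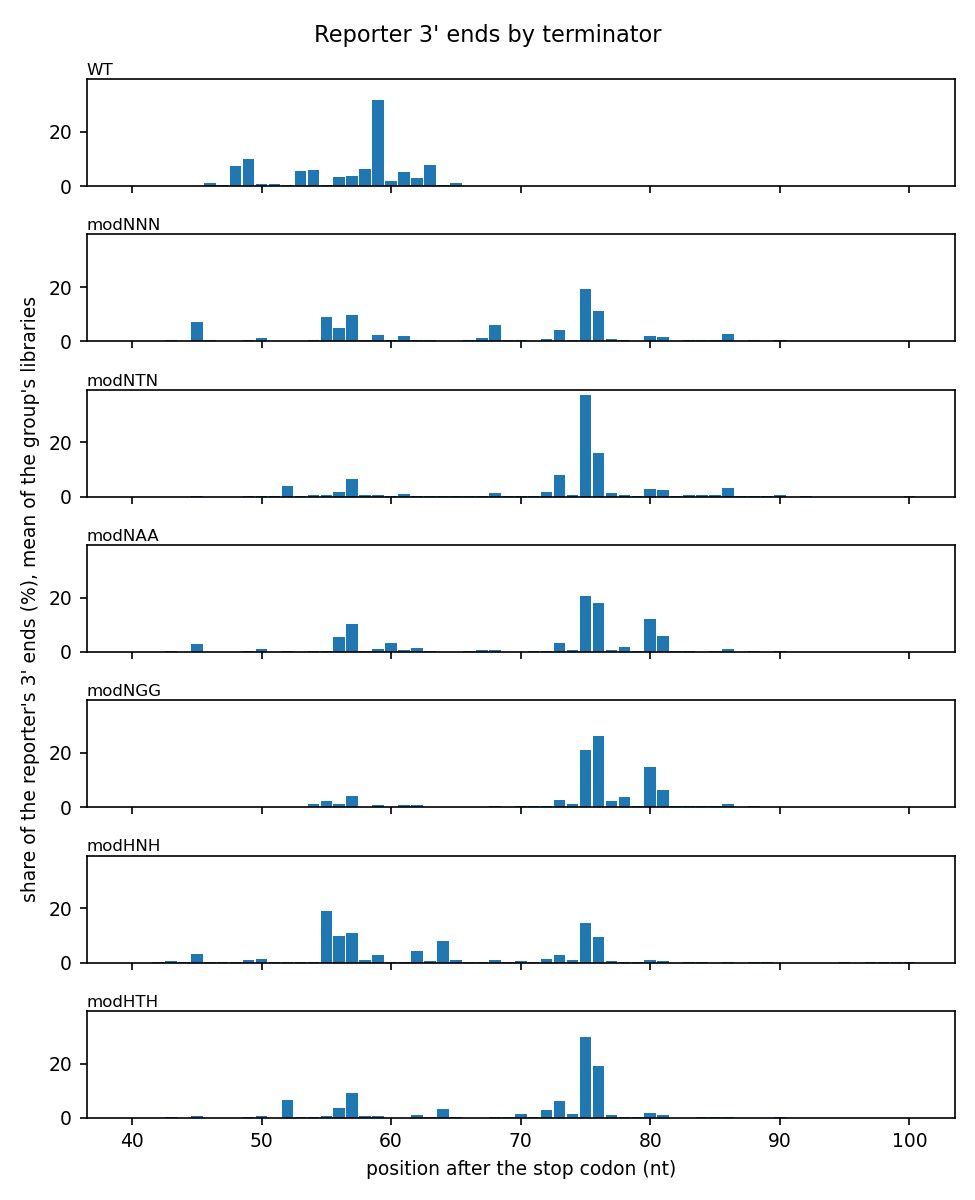
Share of the reporter's 3′ ends in percent (vertical axis) at each position after the stop codon in nt (horizontal axis), as the mean of each group's libraries, with a panel for each terminator. The leading bar lies at 59 nt for WT, at 55 nt for modHNH, at 76 nt for modNGG and at 75 nt for the other 4 terminators.

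The mean 3′ end position differed between the 7 reporter groups (permutation test of the F ratio with 100000 resamples, p = 0.00033, adjusted p = 0.0013 over the 12 tests on reporter 3′ ends). It lay 11.7 nt further in the 9 modified libraries than in the 2 WT libraries (two-sided exact permutation test, p = 0.018, the smallest that 55 splits can give, adjusted p = 0.027). WT is a single construct, so counted by construct this comparison cannot pass. With positions within 10 nt merged it no longer passed (exact permutation adjusted p = 0.055). The share at 75 nt was 15.7 percentage points higher in the 3 libraries with T than in the 6 modified libraries without it, and higher in 3 of 3 (two-sided exact permutation test, p = 0.012, the smallest that 84 splits can give, adjusted p = 0.027). Counted by construct, 2 terminators with T against 4 without make 15 splits, whose smallest exact p is 0.067. The mean position did not separate terminators with and without T (difference 2.40 nt, exact permutation p = 0.38). None of the 12 tests on each of PGK1, RPS3, TSA1 and plasmid URA3 passed after adjustment, which with so few libraries does not show that their ends stayed in place. The mean position on plasmid URA3 was 26.7 nt in modHTH, against 18.6 ± 0.2 nt in WT (SD, n = 2), and its site at 19 nt held 30.9% against 45.2% ± 0.2. The PGK1 site at 158 nt held 31.9% in modHNH and 32.1% in modHTH, against 44.4% ± 0.5 in WT (SD, n = 2). It held 41.9% in modNGG. The native RPS3 site at 59 nt held 20.7% in modNGG, 19.5% in modHNH and 16.5% in modHTH, against 34.5% ± 2.8 in WT (SD, n = 2). How far the reporter's 3′ end shares in these lone libraries follow such shifts cannot be told apart from the terminator. The reporter with the WT terminator shares that sequence with native RPS3, and how reads within it were assigned is not given in the sources used here.

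Fewer of the reads counted on the modNNN reporter reappear as 3′ ends in the 200 nt window. The ends listed there came to 87.9% ± 4.1 of the modNNN reads (SD, n = 2), against 99.8% ± 0.1 in WT and 97.3% ± 0.1 in modNTN (SD, n = 2 each). Plasmid URA3 showed 80.8% ± 1.8 in modNNN and 82.3% ± 0.2 in WT (SD, n = 2 each). Where the remaining reads end was not tested. With the reporter read as ends within the window, the modNAA value against modNNN was −1.05 and its edgeR adjusted p was 0.13.

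The third comparison was of 5′P end positions in the deposited window around the stop codon. The reading frame most used by the control genes held 35.7% ± 0.6 of reporter ends in WT (SD, n = 2) and 36.1% in modHTH, not far above an even spread over 3 frames. The test of that share over the 7 groups gave a permutation p of 0.66, but the ceiling described below caps the share unequally, so this does not show that the groups are alike. Ends past the stop codon made up 0.266% ± 0.037 in WT, 0.829% ± 0.016 in modNNN, 0.716% ± 0.187 in modNAA and 0.315% ± 0.046 in modNTN (SD, n = 2 each), and 0.674% in modHTH, 0.320% in modHNH and 0.156% in modNGG, with a permutation p of 0.028 over the 7 groups and an adjusted p of 0.10 over 15 tests. The deposited 5′P counts have a ceiling: 5 to 42 positions of the reporter share the highest count of a library and hold 10.1% to 30.8% of its ends. The ceiling thus also affects, unequally, the totals from which the share past the stop codon is taken. These totals ran from 1632 ends in modHTH to 11574 in modNGG, so such small shares rest on few ends. Shares at the leading positions, at −268, −267 and −228, restate that ceiling and are not interpreted.

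The fourth comparison was of host genes with and without the reporter. A total of 20 of 5268 genes were lower in the reporter libraries and 0 were higher (edgeR quasi-likelihood test, adjusted p under 0.05). They included the high-affinity hexose transporters HXT7 (415 ± 75 CPM, n = 11, against 658 ± 32, n = 2; log2 fold change −0.75, SE 0.11) and HXT6 (log2 fold change −0.71, SE 0.13), which are near-identical copies, so their reads are uncertain. Also lower were the aldehyde dehydrogenase gene ALD3 (70.5 ± 7.7 CPM against 138 ± 43; log2 fold change −0.96, SE 0.15, chromosome XIII, 599297 to 601131), the cell wall gene SPI1 (−0.81, SE 0.14) and TPS1 (−0.69, SE 0.13), which encodes a trehalose synthase subunit. Among the others were YNL194C (−1.54, SE 0.24), CPP3 (−1.32, SE 0.24), RTC3 (−0.82, SE 0.15), TMA10 (−0.79, SE 0.14), FMP16 (−0.71, SE 0.13), RTN2 (−0.71, SE 0.14) and SDH4 (−0.69, SE 0.14), a succinate dehydrogenase subunit. All 20 genes kept their direction in the fit with 4 reporter groups, which called 0 of them. For each of the 20, the libraries with and without the reporter did not overlap. A fit on fewer of the same libraries could therefore hardly turn a direction, and this is no further support. Of the 20, 18 were called in DESeq2, 20 with the replicate block and 9 with the coding length trend removed. DESeq2 gave no adjusted p to 2655 genes here, so it corrected for fewer genes. With each library left out in turn, HXT7 ranged from −0.82 to −0.69, SPI1 from −0.86 to −0.77 and ALD3 from −1.31 to −0.64. The count rests on the whole set of libraries. It was 0 with only the 4 reporter groups that have 2 usable libraries, 2 and 0 without the first and second library of the control, and 301 without the first modNNN library. Without the second modNNN library it was 77, and without the first or second WT library 130 or 48. The fit first planned, on all 16 libraries, called 101 higher and 187 lower genes, 16 of them among the 20, but it also made false calls on simulated data without changes.

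Of the lists fixed before the data were examined, the general stress response was lower with the reporter, with 5 of 24 members passing over all genes and 14 adjusted over the list alone (limma camera, adjusted p = 2.5e-12; adjusted p = 0.53 with an estimated correlation). In the respiratory chain list, 0 of 24 members passed over all genes and 10 were lower adjusted over the list alone, among them COX4 (−0.50, SE 0.14) and QCR8 (−0.43, SE 0.12), with a camera adjusted p of 5.8e-06 and an adjusted p of 0.53 with an estimated correlation. Cleavage and polyadenylation factors lay above 0 in 12 of 12 members, with 4 higher adjusted over the list alone, PCF11 (0.65, SE 0.18), CFT2, YSH1 and RNA15 (camera adjusted p = 0.0022; adjusted p = 0.53 with an estimated correlation). The mean log2 deviation of this list was highest in the lone libraries modHTH (0.23) and modNGG (0.17), with modHNH at 0.11, and lay at −0.15 and −0.083 in WT against −0.21 and −0.20 in the control. RNA decay machinery lay above 0 in 19 of 24 members (camera adjusted p = 0.0029; adjusted p = 0.62 with an estimated correlation), which does not follow the reporter alone. Its mean log2 deviation was 0.19 in modNGG, 0.29 in modHNH and 0.32 in modHTH, but −0.098 and −0.16 in the WT libraries, against −0.091 and −0.22 in the control. The camera call was lost with the 4 reporter groups of 2 usable libraries (adjusted p = 0.14), with the coding length trend removed (0.067) and without the second control library (0.058). Cytosolic ribosomal proteins, glycolysis and heat shock chaperones had lower values and ribosome biogenesis higher ones, with camera adjusted p-values of 0.00043, 0.0015, 0.015 and 0.019. Their adjusted p-values with an estimated correlation were 0.83, 0.83, 0.53 and 0.62. With the coding length trend removed, the camera calls of cytosolic ribosomal proteins and ribosome biogenesis were lost (adjusted p = 0.29 and 0.12). Those of ribosomal proteins and glycolysis were lost without the first control library, those of chaperones and ribosome biogenesis without the second, and that of ribosome biogenesis also without the modNGG library. Over all 10 comparisons, 38 of 150 list tests passed with camera's preset correlation, 0 with an estimated correlation and 0 in fry.

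The last comparison was of host genes between constructs, whose stated difference is only the reporter's terminator. The seripauperin gene PAU5 differed between modNNN and WT, at 23.8 ± 3.3 against 2.27 ± 1.09 CPM (SD, n = 2 each; log2 fold change 3.35, SE 0.42, edgeR adjusted p = 0.0014), as the only gene of 5268. WT is the group that stands apart for PAU5, since the 2 control libraries had 23.3 and 16.2 CPM, and the other modified libraries 20.1 to 29.7 CPM. Its family has near-identical copies, so its reads are uncertain, and 0 genes passed without the second WT library, against 14 without the first modNNN library. In modHTH against modNNN, 3 genes rose: the zinc transporter gene ZRT1 (log2 fold change 1.96, SE 0.34), the 14-3-3 protein gene BMH2 (1.81, SE 0.32) and the asparagine synthetase gene ASN1 (1.45, SE 0.26), each with an edgeR adjusted p of 0.043. These 3 calls rest on 1 modHTH library, and 0 genes passed without the first modNNN library or either modNTN library, against 669 without the second modNNN library. Without either library of the control 1 gene passed, and without either WT library 5. With RLE size factors, the filter of at least 50 reads in a group mean, the replicate block or the coding length trend removed, 0 genes passed, and DESeq2 called 51. With each library left out in turn, the log2 fold change ranged from 1.38 to 2.41 for BMH2, 1.12 to 1.84 for ASN1 and 1.86 to 2.05 for ZRT1. In the other 7 contrasts, 85 to 833 genes had an unadjusted edgeR p under 0.05, where a share of 0.05 of the 5268 genes is expected without changes. The difference between the effects of T (85), modHTH against modHNH (96) and modNTN against modNNN (101) lay under that share. Above it lay modHTH against modNTN (657) and, against modNNN, modNAA (327), modNGG (761) and modHNH (833). After adjustment, edgeR called 0 genes in these 7 contrasts and DESeq2 0 to 3. These counts too rest on the libraries: without the second modNNN library 357 genes passed for modNGG and 528 for modHNH against modNNN. With only the groups compared, 196 passed for modHTH against modNTN. All contrasts against modNNN share its 2 libraries.

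Among the lists, the general stress response had higher values in modNNN than in WT (21 of 24 members above 0, camera adjusted p = 1.0e-06; adjusted p = 0.53 with an estimated correlation), with HSP12 at 0.73 (SE 0.24) and 0 members passing adjusted over the list alone. Against modNNN, RNA decay machinery had higher values in modHNH and modHTH, with medians of 0.30 and 0.40 on the log2 scale (camera adjusted p = 0.00070 and 0.00085; adjusted p = 0.62 with an estimated correlation in both). The list also passed camera in modNGG, a lone library without H, so the change is not particular to H. That modNGG call was lost in some fits with a library left out. The modHNH and modHTH calls were lost with the coding length trend removed (camera adjusted p = 0.057 and 0.073), and both groups are lone libraries that stand apart on the main axis described below. The list's members with the smallest p included the helicase gene DHH1 (1.44, SE 0.41 in modHNH) and NMD2 (0.66, SE 0.21 in modHTH). Histone genes had lower values in modHNH than in modNNN in 8 of 8 members, with HHT2 (−0.76, SE 0.21) and HTB1 (−0.77, SE 0.24) lower adjusted over the list alone (camera adjusted p = 0.00034; adjusted p = 0.62 with an estimated correlation). Puf3 targets, listed because the T motif holds TGTA, the start of sites bound by Puf proteins, passed in none of the 10 comparisons (lowest camera adjusted p = 0.44). Whether the whole T motif, TGTACAATA, is a site of Puf3 rather than of another Puf protein was not tested. The list result therefore says nothing about the T motif.

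The libraries also differed along a main axis of host genes that did not follow the groups alone. This first principal component held 38.7% of the variance over 13 libraries. The modHTH, modHNH and modNGG libraries lay at 22.5, 21.5 and 13.3, the WT libraries at −14.3 and −13.0, and the 2 modNNN libraries at −17.7 and 5.72. Long coding genes stood higher than short ones toward modHTH (Spearman's rho of gene weight with coding length 0.41) relative to each gene's mean. The upper quartile of length minus the lower came to 0.314 on the log2 scale in modHTH and −0.229 and 0.019 in the 2 modNNN libraries. DHH1, PUF3 and DCP1 of the RNA decay list, and BMH2, are among the genes with most weight toward modHTH, so their differences go along with the axis. PAU5 is among them too, although the first modNNN library, at the WT end, had 21.5 CPM of PAU5. Native RPS3 ends at 59 nt, a site with 39.9% and 24.4% of ends in the 2 modNNN libraries, went with it.

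**Figure D3:**
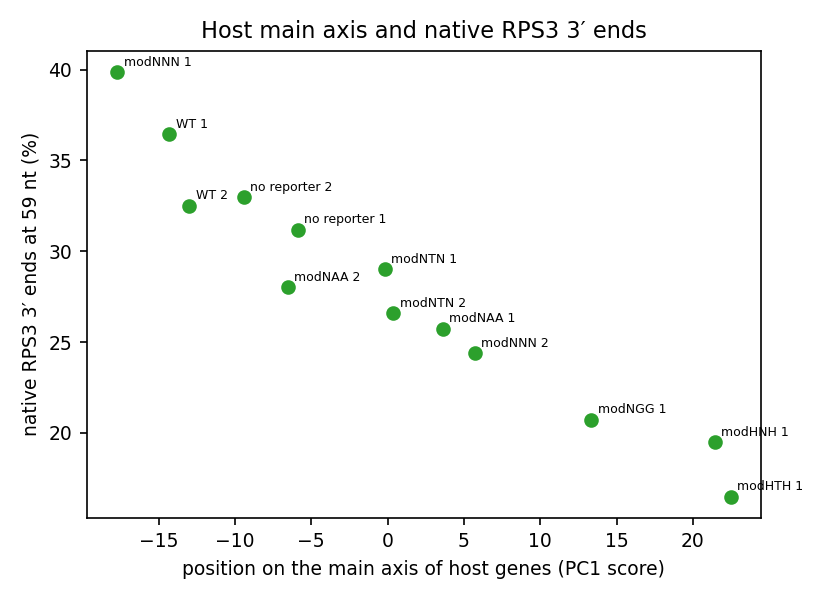
Score of each of the 13 libraries on the main axis of host genes (horizontal axis, no unit) and share of native RPS3 3′ ends at 59 nt in percent (vertical axis); each point is a library. The modHTH library has the highest score (22.5) and the lowest share (16.5%), and the first modNNN library the lowest score (−17.7) and a share of 39.9%.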

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

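All tests of explanations in this part were chosen after the results were seen. The effect of T on the reporter differed with H: −1.73 on the log2 scale (SE 0.30) between modHTH against modHNH and modNTN against modNNN. It is listed because the difference itself was tested, with an unadjusted p of 4.8e-05 in edgeR, an adjusted p of 0.25 over all rows and of 8.7e-05 over the reporter contrasts alone. It passed in DESeq2 (adjusted p = 0.00011) and with library totals (0.016). A lower plasmid dose would lower URA3 too, but relative to plasmid URA3 the difference was −1.42, against an SD of 0.41 expected for 4 single libraries from the replicate spread, which argues against dose as the whole cause. Whether the modHNH and modHTH libraries stand apart for another reason cannot be told apart from the motifs, since each group has 1 usable library. The biological explanation, a joint action of both motifs, stays open and untested beyond this.

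The main axis of variation among host genes held 38.7% of the variance and put modHTH (22.5), modHNH (21.5) and modNGG (13.3) opposite the WT libraries (−14.3 and −13.0). Sequencing depth is argued against, because 106% of the gap between modHTH and WT was left at equal depth. A trend with coding length is argued against as the whole cause, with 91.3% of the gap left once it was removed. Length does follow the axis, though: the mean log2 deviation of long minus short coding genes was 0.314 in modHTH, 0.307 in modHNH and 0.192 in modNGG, against −0.217 and −0.161 in WT. A cause that acts on length among other things, such as RNA or library quality, stays open. The terminator alone is argued against too, since the 2 modNNN libraries lay 58.3% of the whole range apart. A library-wide change that also moves the 3′ ends of control genes is consistent with the correlation of the axis with native RPS3 ends at 59 nt (r = −0.97), and what such a change is stays open.

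The lower general stress list with the reporter kept an adjusted camera p of 5.8e-13 with the coding length trend removed and of 8.2e-19 without the groups of 1 usable library, so neither accounts for the whole of it. Both values use camera's preset correlation, and with an estimated correlation the list did not pass (adjusted p = 0.53). The state of the control cells at harvest was not tested and stays open.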

How the results depend on the processing

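The alternatives added after the data were seen are the coding length trend, the ratio to plasmid URA3, the 4 groups with 2 usable libraries, the 5′P ceiling and the adjustment over the reporter contrasts alone; the fit on 13 libraries was also chosen then. The direction of the reporter difference for modNAA and modHTH held under every alternative run, but the calls did not. The usable modNAA and modHTH libraries lay below every modNNN and modNTN library in reporter CPM. Most alternatives reuse these libraries and could hardly turn the direction, so its keeping is little further support. For modNAA against modNNN the call was lost with all 14 reporter libraries (−1.23), with only the groups compared (−1.23), with the replicate block (−1.22) and with reads from the 3′ end table (−1.05). With all 14 reporter libraries the modHTH calls against modNNN (−1.91) and modNTN (−2.20) were lost as well and modNGG turned to −0.042. The differences of modHTH from modHNH and between the effects of T passed with DESeq2 (−1.43 and −1.72), with library totals (−1.45 and −1.78) and when adjusted over the reporter contrasts alone (−1.43 and −1.73), where modNNN against WT (−0.45) passed too. Relative to RPS3 reads, modHNH against modNNN was −0.049 and modHTH −1.45. Relative to plasmid URA3, modNNN against WT was 0.058, modNGG 0.16, modHNH −0.51 and the difference between the effects of T −1.42. With each library left out in turn, modNAA against modNNN ranged from −1.38 to −1.08, modHTH against modNNN from −1.75 to −1.63 and modHTH against modNTN from −2.11 to −1.86, with calls lost in some of them. The cause was not tested.

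The count of genes lower or higher with the reporter, 20 as reported, was 59 with DESeq2, 61 without a filter, 11 without the coding length trend, 2 for the WT reporter alone, 0 with the 4 groups of 2 usable libraries and 288 with all 16 libraries. Between constructs, all 16 libraries gave 5 genes for modNNN against WT, 2 for modNAA, 84 for modNGG, 152 for modHNH and 255 for modHTH against modNNN, and 58 for modHTH against modNTN. DESeq2 gave 2 for modNNN against WT, 1 for modNGG, 1 for modHNH, 51 for modHTH and 3 for modHTH against modNTN. Only the groups compared gave 3, 4 and 7 for modNGG, modHNH and modHTH against modNNN and 196 for modHTH against modNTN. For modHTH against modNNN, RLE factors, the stricter filter and the coding length trend gave 0, and library totals and no filter gave 5. Whether the replicate numbers pair the libraries is left open: 5 of 10 pairs of groups had a correlation over 0.1 (range −0.31 to 0.32). With each library left out in turn, the counts ranged from 0 to 301 for the reporter, 0 to 14 for modNNN against WT, 0 to 1 for modNTN, 0 to 7 for modNAA, 0 to 357 for modNGG, 0 to 528 for modHNH and 0 to 669 for modHTH against modNNN, and 0 to 10 for modHTH against modNTN; the highest 3 came without the second modNNN library. With a replicate block the counts were 68 for the reporter, 4 for modHNH and 0 for modHTH against modNNN.

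The number of lists that passed was 0 in every comparison with an estimated correlation and with fry. With all 16 libraries it was 0 for modNTN, modHTH against modHNH and the difference between the effects of T, 1 for modNAA, modHTH against modNNN and modHTH against modNTN, and 2 for modNNN against WT. There glycolysis in modHTH against modNTN turned, at an adjusted p of 0.33 (signed −0.33). Without the coding length trend it was 5 for the reporter, 3 for modNNN against WT, 2 for modNTN and 1 each for modHNH and modHTH. With each library left out in turn it ranged from 2 to 6 for modNNN against WT, 2 to 4 for modNTN, 1 to 2 for modHTH against modNNN and 1 to 3 for modHTH against modNTN. Cytosolic ribosomal proteins turned in modNNN against WT without the first WT library and in modNTN without the first modNNN library; their adjusted p, signed by direction, ranged from −0.92 to 0.76 and from −0.046 to 0.83.

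For 3′ ends, merging positions within 10 nt left the mean position 10.4 nt further in modified libraries, past the threshold no longer (adjusted p = 0.055). With each library left out in turn it ranged from 11.1 to 12.6 nt, and with 1 WT library the 10 splits cannot pass. For 5′P ends, none of the differences that turned had passed the test. The leading frame's difference between T and no T was 0.86 percentage points without positions at the ceiling, and −0.52 to 0.082 with each library left out; for modified against WT it ranged from −0.20 to 0.67. The share past the stop codon had an F ratio of 16.1 over the 7 groups with at least 10 reads per position (adjusted p = 0.046) and of 6.95 to 93.0 with each library left out, and its difference between T and no T turned to 0.040 with that minimum. The share past the stop codon rests on few ends and on totals that the ceiling affects unequally, so its pass with that minimum is not interpreted. The shares at the leading positions restate the ceiling. Their rows for T, −0.18 to 0.40, turn in sign and are not interpreted. Depth left the second libraries of modNGG, modHNH and modHTH without usable values, so these groups have 1 library each.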

Other observations

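The list tests in this part were planned, and the correlations with the main axis were chosen after the data were seen. Ribosome biogenesis passed camera in 7 of the 10 comparisons, glycolysis in 5, histones in 4, heat shock chaperones in 3 and sulfur assimilation in 1, and in none with an estimated correlation. Mitochondrial ribosomal proteins (lowest camera adjusted p = 0.072), amino acid biosynthesis (0.22), pyrimidine synthesis (0.28) and genes of mating type a (0.098) passed in none.

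Native RPS3 transcripts ended at 59 nt in 34.5% ± 2.8 of cases in WT libraries (SD, n = 2) and in 16.5% in modHTH (95% Wilson interval 15.1 to 18.0). Over 13 libraries this share correlated with the main axis of host genes (Pearson's r = −0.97, permutation p = 1e-05, the smallest the resamples can give; Spearman's rho = −0.98; adjusted p = 4.0e-05 over 4 relations), and without the 2 libraries farthest out r was −0.96. For the leading TSA1 site r was −0.91 (adjusted p = 0.00010) and −0.78 without those 2. For the leading PGK1 site r was −0.81 (adjusted p = 0.0013) and −0.47 without them (permutation p = 0.14 over 11 libraries), so that relation rests on those 2 libraries. The total of reads gave r = −0.31 (permutation p = 0.30).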
